A study of Mus musculus with 4 samples.

How the data were processed

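The material was total RNA from neurospheres of wild-type mice and of the Dll1 mutant lines Dll1-3 and Dll1-5, hybridised in pairs to 4 Agilent arrays of 43790 spots, of which 2256 were control spots. Per the labels, replicate 1 of each line had mutant RNA in Cy5 and wild-type RNA in Cy3, and replicate 2 had the dyes swapped, so the replicate number is the dye orientation. The design text describes 2 biological replicates of pooled RNA (3 per pool), each dye-swapped, which with 4 arrays was read to make each line 1 replicate. Whether the 2 arrays of a line held the same pools is not settled by the labels. P-values therefore measure the spread between these samples, and the ratio against wild type leaves out the spread between wild-type pools.

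Scanned intensity values were deposited by the authors as Agilent Feature Extraction 8.1.1.1 output, per the file headers and the submitters' processing notes. Those files also hold a log10 ratio of Cy5 over Cy3 after the scanner software's own background and dye correction, per the file headers. The deposited value table of the series was log10 as well: against the scanner ratios its slope was 1.00 in size on every array, and its r with mutant over wild type was -0.962, -0.956, -0.954 and -0.956, so it was wild type over mutant. Its column medians were -0.03, 0.01, -0.02 and 0.01, where those of the scanner ratios were 0, and how its values were centred and processed is not given in the sources used here. It was used as an alternative only.

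Mean signals were corrected for local background with normexp at an offset of 50, in limma 3.58.1 and R 4.3.3 with the data.table package, version 1.17.8. An offset of 50 compresses the ratios of dim genes. Arrays were normalised with loess within each array (span 0.3), with control spots and spots marked as outliers at weight 0, and ratios were turned to log2 mutant over wild type. Control and outlier spots were left out (50, 78, 115 and 27 outlier spots per array), and saturated spots were kept. Spots of a probe were averaged. Of 41174 probes, 34447 were kept because mutant or wild-type RNA was well above background on both arrays of a line. A gene was represented by its probe of highest mean intensity, which gave 23108 genes, 23106 with values in both lines, and 7629 genes had over 1 passing probe, whose sizes can differ widely. Names came from the RefSeq table of assembly GRCm38.p6 by accession for 13750 genes, by symbol for 2476 and by synonym for 1361, and 5521 kept the file's own name. Probe coordinates are those of the array files, with no build named there, and none was taken from the RefSeq names.

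Median net signals were 78.5, 68.8, 70.8 and 68.2 in Cy3 and 116.2, 115.7, 110.1 and 105.6 in Cy5, against 37.4, 30.3, 33.2 and 30.7 and 13.9, 10.5, 11.5 and 11.4 for negative control spots. Where a probe was well above background on no array of a group, the ratio is given as a bound, and where it was on some of them, the ratio is given with their number; the bound is the brighter group's mean over, per array, the higher of the lowest signal among probes well above background and the dim probe's own signal, from channels after loess and Aquantile. Each array was on a slide of its own, so no slide could be tested as a batch.

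The dye-swapped arrays of a line were averaged first. Both line means were tested against 0 with limma's lmFit and eBayes (1 residual degree of freedom, prior 1.64), with Benjamini-Hochberg adjustment at 0.05. Single lines and the difference between lines had no test, and genes at least 2-fold on both arrays were counted; for the difference, both arrays of one line had to exceed both of the other. For 23 gene lists limma's camera was run with a preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation, rank-based camera and fry. Camera with an estimated correlation draws on the 1 residual degree of freedom of the fit, so a list it did not pass is not thereby shown to be unchanged. List medians per line were set among 10000 random lists matched on intensity, drawn as if genes were independent. Genes were named by rule: Dll1, the Notch receptors and Hes and Hey genes; the 12 highest and 12 lowest over both lines among those past the adjusted threshold and, where fewer passed, those with the smallest unadjusted p that were 2-fold in both lines; the 8 highest and 8 lowest per line and for the difference; and up to 4 members per list. Clone and predicted-gene names were passed over. Some genes the rule names are not reported here. The grouping, tests, gene lists, this rule and the alternatives were fixed before the data were examined, except the omission of genes on chromosomes X and Y.

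Alternatives covered no background correction, an offset of 10, the scanner software's ratios, median centring, Aquantile, the deposited value table, other filters on dim probes, outlier spots kept, the mean of all probes of a gene, each array left out, other thresholds, moderation and set tests, and the 4 arrays as samples with and without a replicate block or with the line as a random block. Arrays of replicate 1 deviated from their line means together (r = 0.751 across genes), as a shared dye orientation would give; no label says whether the replicate number marks shared material.

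The steps were tested on simulated arrays, for the comparison of both lines over 23108 genes with 200 genes altered. With an SD of 0.2 between lines for every gene, limma called 50 of 50 genes at each planted log2 change (1, 2, -1 and -2) and 9 of 22868 unchanged genes. With the spread between lines shuffled from the real line differences, a form written after the first had been run, it called 0 of the altered genes at the adjusted threshold and 48, 50, 44 and 50 at an unadjusted p under 0.05, with fitted medians of 0.94, 1.90, -0.97 and -1.95, and 0 unchanged genes. The forms differ in both the size and the unevenness of the spread. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.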

Results

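Messenger RNA levels were measured in neurospheres, free-floating cultures grown from mouse neural stem cells in serum-free medium with EGF. A pair of lines mutant for Dll1, a ligand of Notch receptors, was compared with wild-type neurospheres on the same mixed 129/Sv and C57BL/6 background. The lines are named Dll1-3 and Dll1-5 in the labels. Each of 4 arrays of 2 colours carried mutant RNA in one channel and wild-type RNA in the other, and each line had 2 arrays with the dyes swapped. Each line's RNA was a pool of 3 preparations, so each line, its arrays read as a dye swap of the same pools, counted as 1 replicate, and n = 2 lines for values over both. Values are log2 ratios of mutant over wild type. For a single line the error is the distance of its dye-swapped arrays from their mean, which on that reading is technical, and for both lines it is the SD between the line means. Between 80.2% and 82.2% of probes were well above background in each channel, and the number of arrays limits the precision.

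The labels were checked first on Dll1. Its log2 ratio was -3.31 and -3.22 on the Dll1-3 arrays and -1.65 and -1.64 on the Dll1-5 arrays, so Dll1 signal was lower in mutant RNA on every array and a signal above background remained on all 4. The mean was -2.46 (SD 1.15, n = 2 lines; limma adjusted p = 0.123). The Dll1 probe lies on chromosome 17 from 13371312 to 13371371, in coordinates whose genome build is not given in the sources used here. Which part of Dll1 the mutants lack is not given there either, so whether this probe tests the deletion is open.

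The comparison with wild type asked which genes differ when Dll1 is mutated, and the Notch receptors and the Hes and Hey transcriptional repressors were read next. Hes5, a repressor that Notch signalling induces in neural progenitors, was at -4.95 ± 0.06 in Dll1-3 and -4.70 ± 0.11 in Dll1-5, a mean of -4.83 (SD 0.18, n = 2; adjusted p = 0.0755, limma). Hey1, another Notch-induced repressor, was at -3.80 ± 0.13 and -1.95 ± 0.02. Hes1, in contrast, was at 0.52 ± 0.03 and 0.44 ± 0.06. Notch3 was at -1.06 ± 0.15 and -0.93 ± 0.09, Notch1 at -0.25 ± 0.15 and -0.59 ± 0.04, and Notch4 at 0.58 ± 0.01 and 2.58 ± 0.05. Hes6, which promotes neuronal differentiation, was at 0.18 ± 0.07 and 0.71 ± 0.12. Heyl stood at 0.10 and 0.29, Hes3 at 0.07 and 0.11, and Hes7 at 0.11 and 0.04. Notch2 was at -0.07 and -0.22, with 1 of its 3 probes of opposite sign, and Hes2 was at 0.43 and 0.24, with 1 of 2 probes opposite. Hey2 was not well above background in mutant RNA, at least 1.6-fold lower than in wild type (limma adjusted p = 0.0792). None of these genes passed the adjusted threshold. The Hes5 probe lies on chromosome 4 from 153454601 to 153454660, and the Hey1 probe on chromosome 3 from 8650364 to 8650423.

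**Figure D1:**
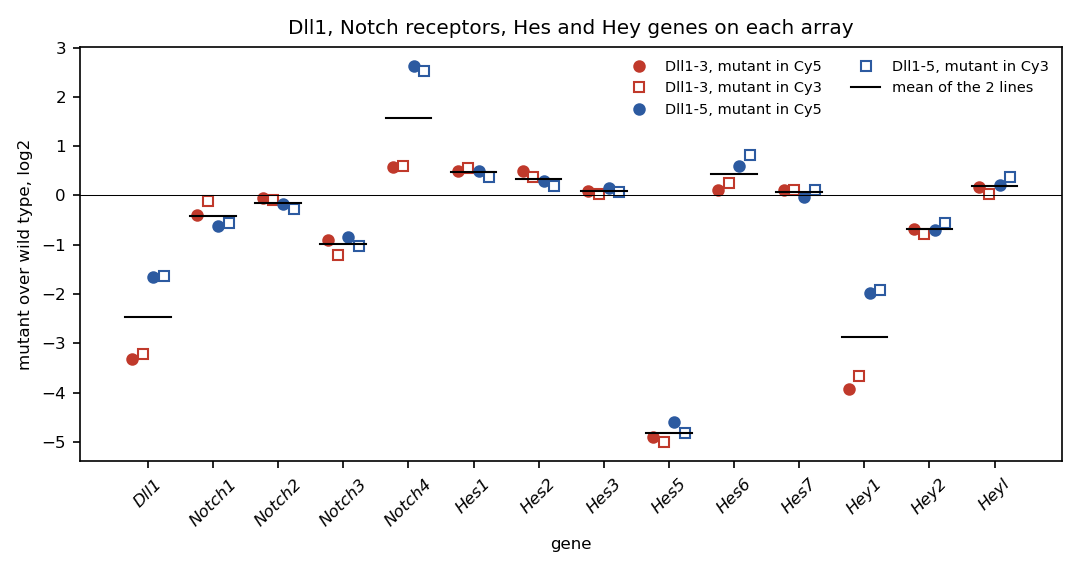
Log2 ratio of mutant over wild type (vertical axis) of Dll1, the Notch receptors and the Hes and Hey genes on each of 4 arrays, by line (colour) and dye orientation (filled or open), with a bar at the mean of both lines. Hes5 sits between -4.59 and -5.01 on every array, while Dll1 and Hey1 lie lower in Dll1-3 than in Dll1-5.

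Over both lines, the genes with the smallest unadjusted p among those 2-fold higher included Scrn1 at 4.31 (SD 0.14, n = 2) and Fkbp10, an endoplasmic reticulum enzyme of collagen folding, at 3.94 (SD 0.04). Car14, a membrane carbonic anhydrase, was at 3.32, Ctsc, a lysosomal protease, at 3.28, and Lpl, lipoprotein lipase, at 3.21. Gadd45a, a DNA damage and stress response gene, was at 3.09 and Nupr1, another stress response gene, at 2.22. Gng2, Flot2, Gas1 and Wdr55 were at 2.73, 2.16, 2.16 and 2.03. Zfp7 was at 2.78, but its other probes lay between -0.03 and 0.30, and 1 of its 5 probes was of opposite sign. On the lower side they included Kcnd2, a voltage-gated potassium channel subunit, at -6.29 (SD 0.28) and Id4, an inhibitor of basic helix-loop-helix factors, at -5.94 (SD 0.15). Eif2s3y, a translation factor gene on the Y chromosome, was at -4.87, Zic1, a zinc finger transcription factor, at -4.78, and Tub at -4.11, with its other probe at -0.13. Omg, a myelin glycoprotein, was at -3.17 and Npr2, a natriuretic peptide receptor, at -2.86, with its other probes at only -0.753 and -0.675. Adgrb3, with 1 of its 3 probes at only -0.48, and Sh3gl3 were at -3.10 and -2.90, and the X-linked Xlr4b and Xlr3c at -3.96 and -2.94. Kcnd2 was above background on 3 of the 4 arrays in mutant RNA. The other probes of Kcnd2, Id4, Scrn1 and Lpl had the same sign but smaller values, at -2.01, -4.00, 2.31 and 1.70. Each of these genes had the same sign on all 4 arrays and an adjusted p of 0.0755 (limma), which missed the threshold of 0.05. Probes for Id4 and Kcnd2 lie on chromosome 13 from 47861358 to 47861417 and on chromosome 6 from 21776606 to 21776665, and those for Scrn1 and Fkbp10 on chromosome 6 from 54650285 to 54650344 and on chromosome 11 from 100245769 to 100245828.

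Of 23106 genes tested with limma on the line means, 0 passed an adjusted p of 0.05, the smallest being 0.0755. At an unadjusted p under 0.05 there were 6345 genes, 2763 higher and 3582 lower, where 1155 would be expected by chance if the lines shared no wild-type RNA. At least 2-fold in the same direction on all 4 arrays were 1018 genes, 388 higher and 630 lower. The same sign on all 4 arrays was found for 11481 genes, or 49.7%, where lines independent of each other, with the shares of 75.8% and 70.4% found within Dll1-3 and Dll1-5, would give 26.7% and shared wild-type RNA would give more. The count of 0 depended on the processing: it was 922 with a smaller background offset, 420 with the scanner software's own ratios, 1678 without Dll1-3 replicate 1 and 1645 without Dll1-5 replicate 2. With the 4 arrays taken as separate samples, which counts as replicates what the design text was read to call repeats of the same pools, limma called 7728 genes, or 6683 with the replicate number as a block and 6613 with the line as a random block.

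Genes of the cell cycle rose as a group. Of 65 members measured, 53 rose, 0 fell and 12 were not past the threshold when p-values were adjusted over the list alone, against 0 over all genes tested. The median was 1.29, or 1.66 in Dll1-3 and 1.01 in Dll1-5. Cyclin genes Ccnd2 and Ccnd1 were at 2.54 (SD 0.31, n = 2) and 1.97 (SD 0.44), the mitotic kinesin Kif20a at 2.32 (SD 0.77) and the spindle checkpoint kinase Bub1 at 2.06 (SD 0.59). Limma's camera with a preset correlation gave an adjusted p = 5.52e-21. The call was lost with an estimated correlation (camera adjusted p = 0.764). That form rests on 1 residual degree of freedom and passed none of the 23 lists. It also lost the neuronal list, whose estimated correlation of 0.007 lay below the preset 0.01. Its losses, here and in the lists below, are therefore not by themselves a sign of correlated genes. For the cell cycle list the estimate was 0.712, far above the preset.

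Astrocyte markers fell as a group, with a median of -1.01 over 45 members. Adjusted over the list alone, 27 fell, 2 rose and 16 were not past the threshold, against 0 over all genes. Ttyh1 was at -4.21 (SD 0.89, n = 2), with 1 of its 5 probes at -0.07, the lipoprotein gene Apoe at -3.75 (SD 0.29), with a wild-type signal saturated on 2 of the 4 arrays, which can compress its ratio, the bicarbonate transporter Slc4a4 at -3.41 (SD 0.33) and the metalloproteinase inhibitor Timp3 at -3.05 (SD 0.82). The other Slc4a4 probes were at only -0.56 and -0.79. Camera's adjusted p = 1.38e-07 became adjusted p = 0.764 with an estimated correlation. The oligodendrocyte lineage list had a median of -0.11 and a mean of -0.61, and adjusted over the list alone 12 of 34 members fell, 2 rose and 20 were not past the threshold, against 0 over all genes. Gpr17 was at -4.08, with 1 of 2 probes opposite, Omg at -3.17 and Lims2 at -2.78, while Cspg4, the NG2 proteoglycan gene of oligodendrocyte progenitors, was at 2.59. Camera's adjusted p = 0.0102 became adjusted p = 0.764 with an estimated correlation. Of 39 neuronal markers, 13 fell, 0 rose and 26 were not past the threshold adjusted over the list alone, against 0 over all genes, with a median of -0.09 and a mean of -0.58. The granin-family gene Scg3 was at -2.62, the microtubule gene Map2 at -1.99 and Chgb at -1.75, with 1 of 2 probes opposite. Camera's adjusted p = 0.0102 became adjusted p = 0.764 with an estimated correlation.

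The list of neural stem cell and radial glia genes had a median of -0.26 and a mean of -0.58. Adjusted over the list alone, 13 of 41 fell, 7 rose and 21 were not past the threshold, against 0 over all genes. Besides Hes5 and Zic1, Lrig1, a negative regulator of growth factor receptors, was at -2.48 (SD 0.04, n = 2). Pax6, a transcription factor of cortical progenitors, was at -1.86 in Dll1-3 and at least 9.11-fold lower in Dll1-5, where it was not well above background, with 1 of 3 probes opposite. Camera's adjusted p = 0.0313 became adjusted p = 0.764 with an estimated correlation, and it was 0.179 with median centring in place of loess. Over 20 alternatives it ran from 0.000234 to 0.764.

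Cholesterol and lipid synthesis genes had a median of 0.49. Adjusted over the list alone, 11 of 29 rose, 2 fell and 16 were not past the threshold, against 0 over all genes. Stard4, a sterol carrier, was at 2.18 (SD 0.98, n = 2) and Cyp51, a sterol demethylase gene, at 1.29 (SD 0.03). Camera's adjusted p = 0.00299 became adjusted p = 0.764 with an estimated correlation. The interferon and antigen presentation list had a median of 0.24 and a camera adjusted p = 0.044, again adjusted p = 0.764 with an estimated correlation, yet 0 of its 52 members passed adjusted over the list alone and 0 over all genes, with 6 higher and 5 lower at an unadjusted p under 0.05 in limma. The chemokine Cxcl10 was at 3.32 in Dll1-3 and 1.61 in Dll1-5, and Lgals3bp at 1.59 and 1.05. Oasl2 was at 2.92 in Dll1-3, with 1 of its 2 wild-type channels there above background, and not well above background in either channel of Dll1-5. H2-K1, a class I histocompatibility gene, was at -0.36 and -2.67, with 1 of 3 probes opposite. The camera call on this list was lost without Dll1-3 replicate 2, at an adjusted p of 0.0678, and over 20 alternatives it ran from 0.02 to 0.764. For each of these 7 lists the highest adjusted p over the alternatives was 0.764, and for the cell cycle list the lowest was 2.86e-29.

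**Figure D2:**
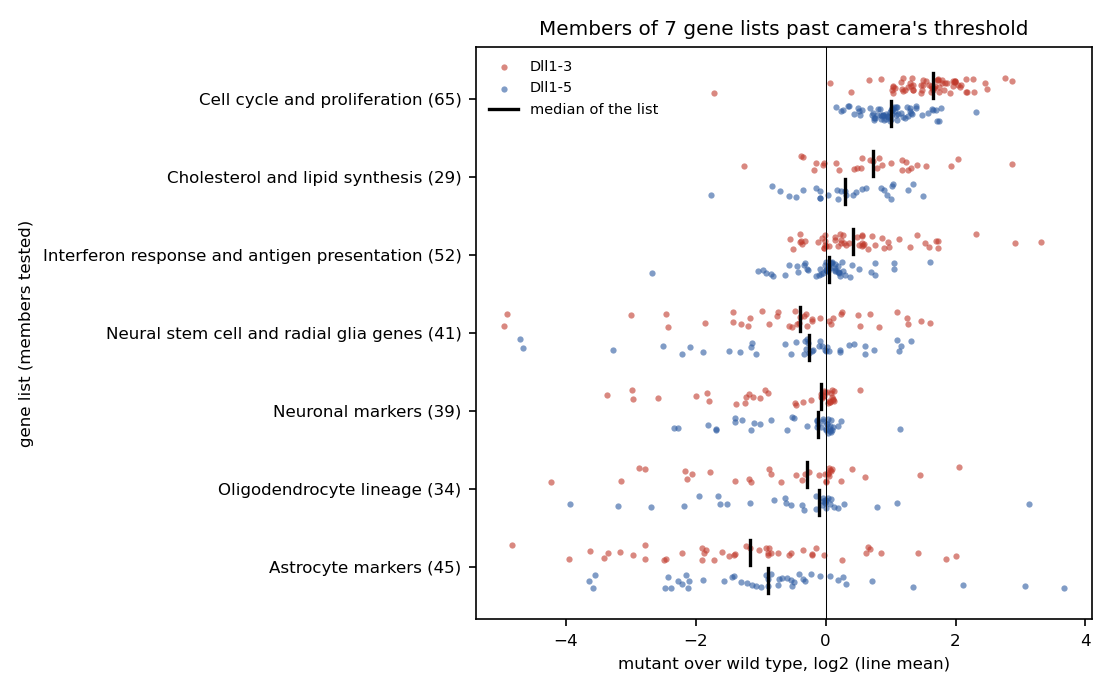
Log2 ratio of mutant over wild type (horizontal axis) of each measured member of 7 gene lists in each line, with a black bar at the list's median and the number of members in brackets. Medians of the cell cycle list are 1.66 and 1.01, and those of the astrocyte list -1.17 and -0.89.

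In the main setting camera passed none of the other 16 lists, and no member of them passed over all genes tested. Of 34 Notch pathway genes, 1 rose, 1 fell and 32 were not past the threshold adjusted over the list alone (median -0.13, camera adjusted p = 0.186); the ligand gene Dll3 was at -2.82 in Dll1-3 and -1.66 in Dll1-5 and the ubiquitin ligase gene Dtx1 at -0.58 and -2.18. Of 21 Notch target genes, 8 fell, 4 rose and 9 did not pass (median -0.54, camera adjusted p = 0.165, or 0.00261 with the line as a random block, which counts arrays as replicates), among them Sox9, a glial transcription factor, at -2.34. For proneural factors these counts were 2 lower, 0 higher and 26 not past (median 0.00, mean -0.22, camera direction down, adjusted p = 0.57), with Myt1 at -2.48 and Elavl3 at -1.64. Ependymal and choroid plexus genes had 4 lower, 1 higher and 20 not past (median -0.05, adjusted p = 0.329), with the cilia regulator Foxj1 at -1.74 and the BMP antagonist Sostdc1 at 1.31. Among 40 CDK inhibitors and p53 targets, 4 fell, 2 rose and 34 did not pass (median -0.16, adjusted p = 0.539). Gadd45g was at -2.68 and Cdkn2a, which encodes the tumour suppressors p16 and p19Arf, at 1.81 (SD 0.06, n = 2), above background in 2 of the 4 wild-type channels.

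Of 63 growth factor and receptor tyrosine kinase genes of glioma, 16 fell, 8 rose and 39 did not pass adjusted over the list alone (median -0.01, mean -0.29, camera adjusted p = 0.326). The ephrin receptor Epha4, above background on 3 of the 4 arrays in mutant RNA, was at -3.76, Kit at -2.60 and Ednrb at -2.26, while Igfbp2, an insulin-like growth factor binding protein gene, was at 2.22. The other Epha4 probe was at only -1.31. Of 68 mesenchymal and extracellular matrix genes, 15 fell, 7 rose and 46 did not pass (median -0.05, adjusted p = 0.329), with the proteoglycan Ncan at -3.70, the integrin Itgb8, above background on 3 of the 4 arrays in mutant RNA, at -3.01 and osteopontin, Spp1, at 2.97. Of 61 genes of the BMP, TGF-beta, Wnt and Hedgehog pathways, 9 fell, 5 rose and 47 did not pass (median -0.04, adjusted p = 0.435), with the Wnt receptor Fzd1 at 2.88, Gas1 at 2.16 and Tgfb2 at -2.23. Hypoxia and glycolysis genes had 5 higher, 2 lower and 23 not past (median 0.15, adjusted p = 0.219), with hexokinase Hk2 at 1.99. The unfolded protein and heat shock list had 5 higher, 3 lower and 17 not past (median 0.10, adjusted p = 0.329), with the stress gene Trib3 at 2.97 and the heat shock gene Hspa1a at -1.66. The other Trib3 probe was at only 1.16. Of 54 regional patterning homeobox genes 1 fell, 0 rose and 53 did not pass (median 0.02, mean -0.17, camera direction down, adjusted p = 0.898).

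The last lists held markers of other cell types, genes near Dll1 and sex-linked genes. Adjusted over the list alone, 0 of 21 microglia and blood markers passed (median 0.02, mean -0.05, camera direction down, adjusted p = 0.869), with 0 higher and 3 lower at an unadjusted p under 0.05 in limma; Lyz2 was at -0.50 and P2ry12, not well above background in mutant RNA, was at least 1.25-fold lower. Likewise 0 of 26 endothelial, mural and fibroblast markers passed (median 0.06, adjusted p = 0.435), with 3 higher and 3 lower at an unadjusted p under 0.05. Flt1 was at -0.85, with its other probes at 0.085 and -0.31, and Acta2 at -0.82, with its others between -0.12 and 0.10. Neural crest and Schwann cell markers had 2 lower, 1 higher and 16 not past (median 0.06, mean -0.10, camera direction up, adjusted p = 0.771), with the endothelin receptor Ednrb at -2.26 and the myelin gene Pmp22 at 2.01. Of 33 genes listed by name as near Dll1 on chromosome 17, 29 of them placed there by the array file, 1 rose, 1 fell and 31 did not pass (median 0.05, adjusted p = 0.57), with Tcte3 at 1.92 and Fndc1 at 1.79, whose probes used here the file does not place, and Wtap at -1.53, where 3 of 4 probes were opposite. The other Fndc1 probes were at -0.01 and 0.08. Of 10 sex-linked genes 3 fell, 0 rose and 7 did not pass (median 0.01, mean -0.80, camera direction down, adjusted p = 0.33): Eif2s3y, Ddx3y at -2.56 and Kdm5d at -1.03, all on the Y chromosome. For some other genes named from lists another probe of the same sign lay within 0.5 of 0: Sox9 (-0.32), Map2 (-0.23), Cspg4 (0.25), Itgb8 (-0.18), Pmp22 (0.17), Hspa1a (-0.20), H2-K1 (-0.18) and Tcte3 (0.46).

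Read as 1 pooled replicate, Dll1-3 alone was given no test, and genes were counted by size. Among genes with a symbol, the highest log2 ratios after Scrn1 (4.21 ± 0.08) and Fkbp10 (3.92 ± 0.10) were those of Arsa, a lysosomal sulfatase, at 3.77 ± 0.01, Ndrg1 at 3.64 ± 0.26, the meiotic recombination gene Mnd1 at 3.63 ± 0.18, the membrane protein gene Gypc at 3.58, the taurine transporter Slc6a6 at 3.54 and the interferon-induced Ifi27l2a at 3.54. The lowest were Kcnd2 at -6.49 ± 0.20, above background on 1 of the 2 mutant arrays, Fhl1 at -6.10 ± 0.05, Id4 at -6.04 ± 0.40, the serine protease gene Prss23 at -5.58 ± 0.25, with its other probe at -0.33, angiotensinogen, Agt, at -5.01 ± 0.02, Eif2s3y at -4.98, the neural adhesion gene Cntn1 at -4.96 and Hes5. Other probes of Scrn1, Slc6a6, Ifi27l2a and Kcnd2 were at 2.34, 1.66, 2.04 and -1.85 in this line. At least 2-fold in the same direction on both arrays were 2430 genes, 1026 higher and 1404 lower, and the median distance of an array from the line mean was 0.07. Of the cell cycle list 56 members were 2-fold higher and 1 lower, of the astrocyte list 3 higher and 23 lower, and of the interferon list 11 higher and 0 lower. The cell cycle median of 1.66 stood at percentile 100 and the astrocyte median of -1.17 at percentile 0 of 10000 random lists matched on intensity, which draw genes as if independent of each other, with the Notch target median of -0.30 at percentile 3.06. Median centring in place of loess left 1079 genes, and the scanner software's own ratios gave 3910.

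In Dll1-5 alone, among genes with a symbol, Scrn1 (4.41 ± 0.21) and Fkbp10 (3.97 ± 0.08) again led, followed by the extracellular matrix gene Fbln2 at 3.67 ± 0.11, the sodium pump regulator Fxyd6 at 3.59 ± 0.13, the CGRP receptor component Ramp1 at 3.52, the histone gene H2ac19 at 3.46, Fzd1 at 3.44 and Car14 at 3.41. Other probes of Fxyd6 and Ramp1 were at only 0.897 and 0.725 in this line. The lowest were Kcnd2 at -6.09 ± 0.16, Id4 at -5.83 ± 0.32, Lrrn1 at -5.18 ± 0.03, with its other probe at -0.31, the sterol transfer gene Gramd1a at -4.84 ± 0.27, Eif2s3y at -4.76, Hes5 at -4.70, Zic1 at -4.65 and Agt at -4.44. Other probes of Scrn1 and Kcnd2 were at 2.28 and -2.17 in this line. At least 2-fold on both arrays were 1541 genes, 693 higher and 848 lower, with a median distance of an array from the line mean of 0.08. Of the cell cycle list 23 members were 2-fold higher and 0 lower, of the astrocyte list 4 higher and 17 lower, and of the interferon list 1 higher and 2 lower. The cell cycle median of 1.01 and the astrocyte median of -0.89 again stood at percentiles 100 and 0 of the random lists, and the Notch target median of -0.52 at percentile 0.01. Median centring left 681 genes, and the scanner software's own ratios gave 2897.

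The lines were then set against each other, as Dll1-5 minus Dll1-3. Dbx2, a homeobox gene of the spinal cord, was at -4.13 ± 0.02 in Dll1-3 and 0.21 ± 0.10 in Dll1-5, a difference of 4.34. Prss23 differed by 4.23, the tautomerase gene Ddt by 3.85, the transporter gene Slco3a1 by 3.73, the co-chaperone gene Bag3 by 3.68, the transcriptional regulator Lmo1 by 3.67, Fhl1 by 3.54 and Pitpnm1 by 3.44. In the other direction, the linker histone gene H1f0 was at 3.17 ± 0.06 in Dll1-3 and -1.12 ± 0.16 in Dll1-5, a difference of -4.29, and Gramd1a, the gap junction gene Gjc1, Pcolce2 and Klhl22 differed by -4.03, -3.82, -3.69 and -3.49, with Pcolce2 above background on 3 of the 4 arrays in mutant RNA. Other probes of Prss23, Bag3 and Klhl22 differed by only 0.27, -0.04 and -0.29, and those of H1f0 by -1.58 and -1.52. The X-linked homeobox gene Esx1 was at 3.52 ± 0.18 in Dll1-3, while in Dll1-5 it was not well above background in mutant RNA and at least 2.16-fold lower than in wild type. Mnd1 and the homeobox gene Hoxa7 (3.46 ± 0.12 in Dll1-3) were also not well above background in Dll1-5 mutant RNA, and Ndrg1 was at least 2.15-fold higher there against a wild-type channel not well above background. The line means differed at least 2-fold, with both arrays of one line above both of the other, for 1013 genes, 632 higher and 381 lower in Dll1-5. The median difference of the cell cycle list was -0.60 and of the interferon list -0.45, both at percentile 0 of the random lists, while that of the astrocyte list was 0.29, at percentile 99.96. These percentiles are no test, as camera estimated correlations of 0.712 and 0.32 within the first 2 lists. Ratios over all genes also spread less in Dll1-5 (SD 0.574) than in Dll1-3 (SD 0.695). The random lists were matched on intensity and not on size of change. For a list far from 0 in both lines, the percentile therefore does not separate this smaller scale from a change of the list itself. No test applies to 1 line against 1 line; the count was 636 with median centring and 2332 with the scanner software's own ratios.

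Across genes, which are not independent replicates, the line means of Dll1-3 and Dll1-5 correlated with Pearson's r of 0.757 and Spearman's rho of 0.679. Among the genes 2-fold in both lines were Scrn1, Fkbp10, Gadd45a and Spp1 on the higher side and Hes5, Id4, Zic1 and Apoe on the lower. Independent lists of the same sizes would share 30.8 higher and 51.5 lower genes, where 388 and 630 were shared. If both lines were set against 1 wild-type pool with no mutant effect, 100 simulations gave r of 0.497 and 187 higher and 186 lower genes in common. The pool was given the same spread as each mutant line, taken from the line difference, which largely fixes this r in advance. Simulated genes in common needed only line values of at least 1, and the 388 and 630 needed 2-fold on every array. The counts are therefore not directly comparable. The covariance was 0.302 against a simulated 0.104, a difference of 0.199 that depends on the spread given to the pool. Wild-type levels differed 2-fold between the lines in both dyes for 3 genes and mutant levels for 1026, and the labels do not settle whether the wild-type RNA was one pool. Part of the excess may come from shared wild-type RNA, which could not be split into parts of 2 arrays. Chromosome stretches shifted in both lines (below) were not tested as a source of it.

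**Figure D3:**
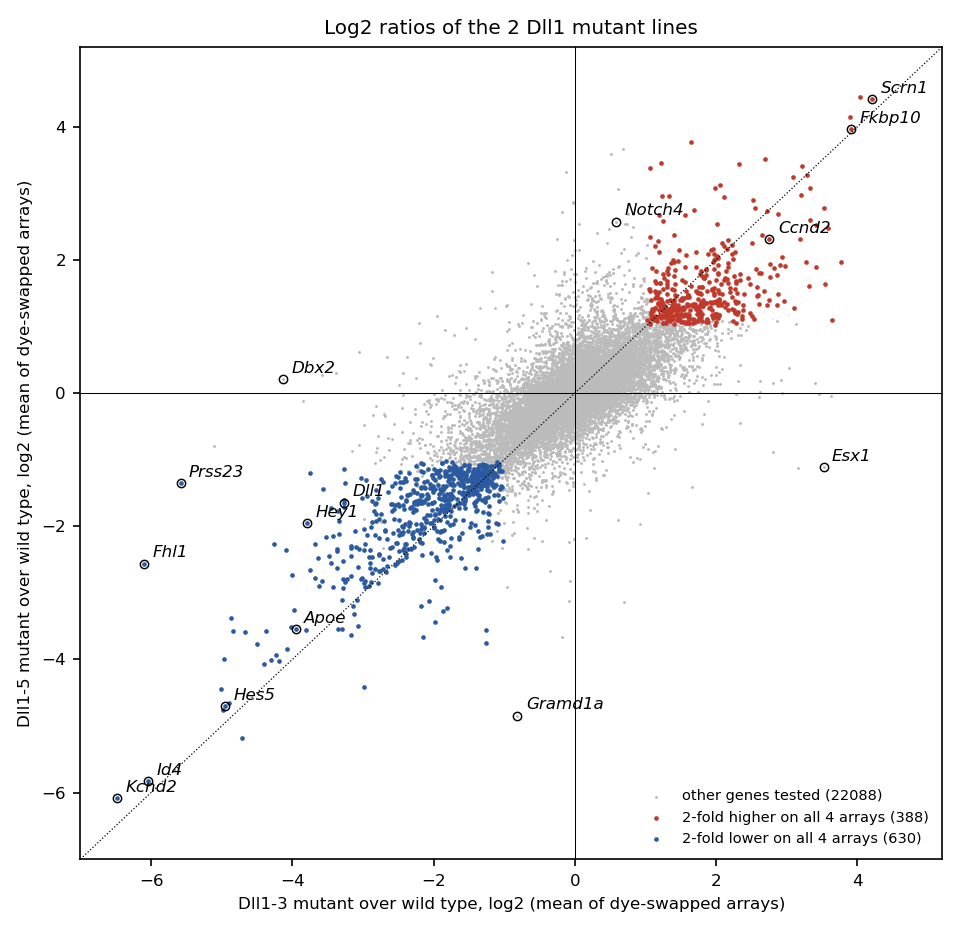
Log2 ratio of mutant over wild type of each gene in Dll1-3 (horizontal axis) and Dll1-5 (vertical axis), with red and blue for those 2-fold higher and lower on all 4 arrays, a dotted line of equal values and examples labelled by symbol. Over all genes r is 0.757, and Hes5, Id4 and Kcnd2 lie far below 0 in both lines.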

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

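The test of brighter against dimmer genes in chromosome windows was fixed before its value was seen, and the other tests of windows here, with the window size and intensity limit, were chosen after results were seen. Among 138 named genes, 10 had mutant over wild type in opposite directions on all arrays of the 2 lines, a difference that was not tested with 1 replicate per line; over all genes this held for 2301, or 10%. As Dll1-5 minus Dll1-3 on the log2 scale, they were Dbx2 at 4.34, Ddt at 3.85, Bag3 at 3.68, though its other probe differed by -0.04, Lmo1 at 3.67, Pitpnm1 at 3.44 and Neurod1 at 1.92, whose Dll1-3 arrays lay 1.37 to either side of their mean. The others were Esx1 at -4.64, whose size is uncertain because its Dll1-5 mutant signal was not well above background, H1f0 at -4.29, Gjc1 at -3.82 and Pcolce2 at -3.69. With the 4 arrays as samples and the replicate number as a block, limma found a line difference for 9120 genes, a test on arrays read as technical repeats of each line.

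The line difference was shifted over long stretches of chromosomes: of 236 windows of 40 neighbouring genes, with the median over all of them (0.04) subtracted, 37 had a median beyond an upper or a lower bound, each kept to by 95% of 200 permuted gene orders, against at most 2 in a permutation. On chromosome 3 from 102.8 to 143.4 Mb (build not given in the sources used here) the median after this subtraction was -0.76 over 120 genes, with 80.8% of them below 0. On chromosome 14 from 3.1 to 19.1 Mb it was 0.63, with 92.5% of genes above 0. Before the subtraction, 79.2% of the former were lower in Dll1-5 and 95% of the latter higher. A dye or array effect was argued against by r = 0.984 over windows between the dye orientations, and a difference in wild-type RNA by window medians whose spread in wild type was 0.083 of that in mutant. Brighter and dimmer genes of a window shifted together (r = 0.756, at most 0.219 in permutations), so copy number differences between the mutant lines may underlie the stretches. Other causes that move neighbouring genes together were not tested. Some windows were shifted against wild type in both lines, for which no bounds were drawn. On chromosome 3 from 3.9 to 31.7 Mb, which covers the Hey1 probe, medians were -0.59 in Dll1-3 and -0.56 in Dll1-5. On chromosome 12 from 101.5 to 108.6 Mb they were 0.32 and 0.63. How far such stretches add to the changes shared by the lines was not tested.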

How the results depend on the processing

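Leaving out genes on chromosomes X and Y was chosen after the data were seen; it gave 0, 2324, 1483 and 972 genes for both lines, Dll1-3, Dll1-5 and the line difference. No list that passed turned to the opposite direction under an alternative, though the balance of lists did (below), and of the values of named genes 1825 stayed within their spread or side of the threshold, 555 passed it and 200 moved. As 0 genes passed in the main setting, a tested gene stayed whenever it again did not pass, whatever its sign. The 1825 are therefore little evidence of stability. The 555 include fits that count arrays as replicates. For both lines, 0 genes passed in limma (6345 at an unadjusted p), and the count was 922 with a normexp offset of 10, 420 with the scanner software's ratios, 3081 at an adjusted p under 0.1 and 1018 by 2-fold change on all arrays; leaving out an array gave 0 to 1678. With the 4 arrays as samples it was 7728 without a replicate block, 6683 with the replicate block and 6613 with the line as a random block; these fits count arrays read as technical repeats, which adds degrees of freedom. The replicate numbers share a dye orientation, and no label pairs animals by them. The count of 2-fold genes on all 4 arrays, 1018, was 1853 with the scanner software's ratios, 384 with median centring and 1812 with the deposited value table (1062 to 1183 with an array left out). In the same order, Dll1-3, at 2430, gave 3910, 1079 and 3833, and Dll1-5, at 1541, gave 2897, 681 and 2829. The line difference, at 1013, gave 2332, 636 and 2325, and 1541 with an offset of 10. By adjusted p without and with the replicate block, Dll1-3 gave 10018 and 13698, Dll1-5 8417 and 12326, and the line difference 4182 and 9120. At 1.5-fold and 3-fold they gave 5067 and 897, 3796 and 502, and 3151 and 263. Leaving out an array gave 2430 to 2953, 1541 to 1917 and 1077 to 1130. The lower ends 2430 and 1541 are the main counts, from leaving out an array of the other line. With an array left out, only the remaining arrays had to reach 2-fold. The counts for a single line and for all 4 arrays could therefore only rise or stay. The correlation of the lines, 0.757, was 0.718 with the scanner software's ratios and 0.716 with the value table of the series (0.733 to 0.751 with an array left out). The cause was not tested for any of these. Of 23 lists, 7 passed camera, 3 up and 4 down, and 6 to 7 with an array left out. Median centring gave 4 up and 3 down, the random block 2 up and 7 down, the replicate block 5 lists, and an estimated correlation and fry 0. Lists gained with median centring were hypoxia (camera adjusted p = 0.0328) and unfolded protein (0.0454). Those gained with the random block were Notch targets (camera adjusted p = 0.00261), glioma growth factors and receptors (0.0149) and sex-linked genes (0.00404). Cell cycle, astrocyte, oligodendrocyte, neuronal and cholesterol lists passed in 18 of 20 alternatives, stem cell genes in 14 (camera adjusted p from 0.000234 to 0.764) and interferon genes in 12. For the lists that passed in 18, the exceptions were an estimated correlation and fry, and every other alternative kept the preset correlation of 0.01. With the replicate block the stem cell and interferon lists were at a camera adjusted p of 0.0528 each. Aquantile left every ratio as it was and so tests nothing. Scanner signal near the negative controls limits folds of dim genes.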

Other observations

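All tests of explanations here were chosen after the results were seen. The values of some genes outside the naming rule, picked after they were seen, follow as values only, with no pattern drawn from them. Cdkn1b, which encodes the inhibitor p27, was at -1.23 in Dll1-3 and -1.26 in Dll1-5 (limma adjusted p = 0.0137, adjusted over the list alone). Cdkn2b, the neighbour of Cdkn2a, was at -0.11 and 2.00, and Cdkn1a, the p21 gene, at 1.67 and 0.58, neither past the threshold over that list alone (limma adjusted p = 0.353 and 0.12). The chromatin gene Hmga2 was at 1.27 and 1.31, Id1 at 1.86 and 1.35, and Sox2 at -1.43 and -1.49 (0.00635, 0.0249 and 0.00635 adjusted over their lists alone), while none of these genes passed over all genes tested. Pdgfra, a receptor of oligodendrocyte progenitors, was at -1.78 and -1.66, opposite to Cspg4 in sign.

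Of the Y-linked genes measured, 3 were lower in both mutant lines, with Eif2s3y at -4.98 and -4.76, while Uty, Sry, Usp9y and Zfy2 (not well above background in Dll1-3) were not, at wild-type levels of 6.76, 6.34, 6.18 and 6.39 (log2), less than 1 above the array floor. With both dye orientations, 12 of 12 values of Eif2s3y, Ddx3y and Kdm5d lay below -0.5, between -0.95 and -5.24, which a dye effect alone would not give. These 3 genes were taken because they were low, so the values are no independent test. The same probes were on every array, so an effect of the probes themselves was not tested. Female mutant cells against male wild-type cells were argued against by Xist, whose highest line mean over 3 probes was 0.16. Absence of the Y chromosome from the mutant cells may account for the 3 genes and cannot be told apart from a loss of their expression: 1 of 4 Y-linked genes well above the array floor, Zfy1, was not lower (0.24 and 0.43), but its probe is not placed on Y in the array file. The criterion first counted Zfy1 against this explanation and was restricted to placed probes only after that value was seen.

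Over both lines, cell cycle genes rose and astrocyte markers fell in limma's camera with a preset correlation. Neither call held in camera with an estimated one (adjusted p = 0.764), a form that rests on 1 residual degree of freedom and passed none of the 23 lists. Within-array loess was argued against, since the gap between the list medians was 2.34 with median centring and 2.29 with loess. Whether the mutant cultures held a lower share of differentiated cells could not be decided. The test took 38 stem cell genes on no differentiated-cell list. Their median of -0.25 (SD 1.43) lay below the cell cycle median of 1.29 (SD 0.47) by slightly more than their SD. Those genes include members of the Notch target list such as Hes5, which a change in Notch signalling could lower whatever the cell types. A change within the remaining cells stays open as well. An atypical wild-type pool shared by both lines cannot be told apart from an effect of the mutation, because only 3 genes differed 2-fold in wild-type RNA between the lines in both dyes, too few to show distinct pools. The Dll1 mutation itself, which the design names, remains a possible explanation that these tests do not isolate.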
